A study of Saccharomyces cerevisiae with 104 samples.

How the data were processed

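Messenger RNA was measured in budding yeast (Saccharomyces cerevisiae) with QuantSeq, a method that reads the 3′ end of each transcript, in 90 libraries of 30 genotypes: wild type (WT) and 29 strains with a point mutation in histone H3 (22 strains) or histone H4 (7 strains). WT and H4Y88A had 4 libraries each, H3T3A and H3T3D had 2 each and the other 26 genotypes had 3 each. A mutant is named by its histone, the original residue, its position and the new residue, so that H3K36A has alanine in place of lysine at position 36 of H3. The 14 ATAC-seq samples of the series were not analysed here.

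The authors deposited raw counts per gene and library, which were used here without change. Their notes name TopHat, HTSeq, featureCounts 1.5.3 and the sacCer3 genome for all samples, without saying which step used which tool, and the strand setting is not stated. The authors also deposited a sheet of log2 fold changes of each mutant over WT, with replicates averaged by a method that is not stated; it was only compared with the values fitted here. The count table held 7122 genes and 5 summary lines of HTSeq, which were left out of the totals. Of the 7122 genes, 6045 (84.9%) matched the RefSeq annotation that gave symbols and positions; the others are given by the name in the count table. The columns carry the genotype and a sample number but no replicate number, and the labels do not say whether replicates were separate cultures, so they may be repeat libraries of one culture. A library is named here by its genotype and sample number, as in WT S133. Between libraries of one genotype, counts differed by more than counting error in each pair checked, by at least 2.09 times in the ratio of chi-square to degrees of freedom. Errors given as ± are standard deviations over libraries; with few counts per library, interval widths from counting alone would cover counting error only.

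Differences were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled by the trimmed mean of M values (TMM), genes were kept by filterByExpr over the genotypes (5822 genes), and a quasi-likelihood negative binomial model with 1 coefficient per genotype was fitted to all 90 libraries, with 60 residual degrees of freedom. Each of the 29 mutants was compared with WT, the 17 pairs of substitutions of one residue with each other, and the mean of the 29 mutants with WT. Tests were two-sided, p values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The common dispersion was 0.0543, a spread of 23.3% between libraries of a genotype. Levels are CPM (counts per 1e+06 counts) after TMM scaling, and log2 levels used a prior count of 2.

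These tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said. Named genes were called, had every library of the mutant on the same side of every library of the reference, and had at least 10 CPM in the higher genotype. The 12 largest increases and decreases were eligible for H3K36A, H3K122A and the mean of the mutants (for the last, genes called in at least 10 mutants), the 4 largest for other mutants and the 2 largest for pairs of substitutions. Up to 4 called members of a list, and the histone and marker genes whether called or not, could be named as well. Where a comparison called 5 genes or fewer, genes outside this rule were named after their values were seen.

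Gene lists were 31 pathways and gene groups with at least 3 tested members. Each was tested in each mutant with camera from limma 3.58.1, with a preset correlation of 0.01 between genes, adjusted within the mutant, and again with the correlation estimated from the residuals. A chromosome was called shifted in a mutant where its median log2 level, relative to the median of all genes and to WT, moved by 0.5 or more in the same direction in every library. Expression profiles were the 5822 log2 fold changes of a mutant over WT, compared by Pearson's r across genes. The mean r of pairs at one residue was compared with that of other pairs by 100000 permutations of the residue labels. All profiles share the 4 WT libraries, so r was also computed on 20 simulated tables without any difference between genotypes.

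Alternatives were DESeq2 1.42.0, the scaling of relative log expression (RLE) in edgeR, no filter on low counts, a model with the libraries of only both genotypes, the mean of the 28 other mutants in place of WT, a minimum log2 fold change of 1, the genes of a shifted chromosome left out, and each library left out in turn. After the data were seen, 3 sets of consecutive sample numbers were defined, and the set was added as a covariate in a further fit. The pipeline was tested on simulated data with 200 changed genes. For H3K36A against WT it found 60% of 2-fold and 96% of 4-fold changes, all with the right sign, with 5 unchanged genes among 161 calls. With 2 libraries (H3T3A) it found 52% and 94%. The changed genes were drawn from those with a mean of at least 10 CPM. The simulated counts held no effect of the sample-number sets, so these shares need not hold for the real libraries. Other splits of the libraries were fitted for each comparison of groups of at least 3 libraries. The result of 1 gene is not reported here.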

Results

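RNA levels were measured in yeast strains that each carry a point mutation in a core histone, to ask which genes change when a single residue of the nucleosome is replaced. The 90 libraries comprised 4 of WT and 4 of H4Y88A, 2 each of H3T3A and H3T3D, and 3 of each of the other 26 mutants. Counts in genes ranged from 768398 to 3143681 per library (median 1507838.5), except for H3K4R S55, which had 24010. The next lowest library detected 6068 genes with at least 1 count, whereas H3K4R S55 detected 3076. Reads placed at more than one site, listed apart from the gene counts, were 1.26 to 8.17 times as many as the gene counts.

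The sample numbers in the columns fall into 3 sets, defined here after the data were seen: 44 libraries with 3 of WT, 22 with none of WT, and 24 with 1 of WT (S133). Within genotypes spread over sets, the set took a median share of 0.142 of a gene's variance (67 libraries), against at most 0.0988 in shuffled sets (100 draws, the real one included). H3K37Q, H3K37R, H4R55A, H3K18A, H3T3A, H3T3D, H3R40K and H3S31D lay wholly in the third set. For these, the set can be told from the mutation only through the third-set libraries of WT (S133) and H4Y88A (S132). The value with the set as a covariate is given beside the count.

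Across the 29 mutants, 2371 differences from WT were called, 1446 increases and 925 decreases, in 1495 of 5822 genes. Counts ranged from 515 genes in H3R40K to 0 in H4K91R, where 167 genes had an unadjusted p under 0.05 in edgeR and DESeq2 also called 0. Here and below, a share of about 0.05 of the 5822 genes would have such a p without any difference. The genes called in the most mutants were CYC1, BNA1, YDR210C-D and YHL006W-A, and only these were called in at least 10.

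**Figure D1:**
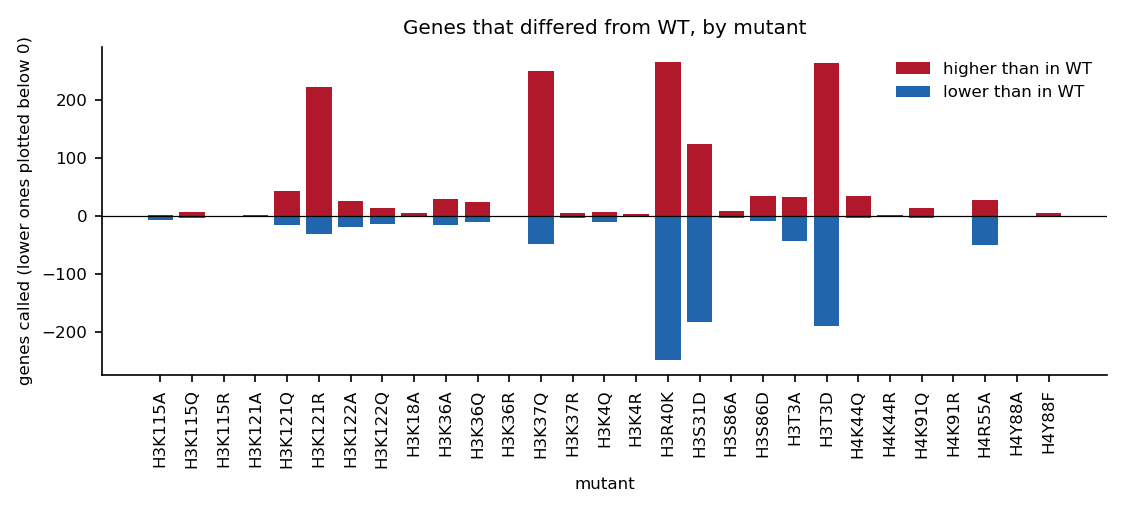
Number of genes called in each of the 29 mutants against WT, with increases and decreases drawn in opposite directions from 0. H3R40K had 266 increases and 249 decreases, and H4K91R had neither.

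CYC1 (YJR048W, chromosome X, 526335 to 526664), which encodes the main cytochrome c of the respiratory chain, was higher in 19 of 29 mutants. The mean of all mutants was above WT (n = 4) by a log2 fold change of 1.11 (adjusted p = 0.000431). The level was highest in H3S86D, at 554 ± 63 CPM (n = 3). BNA1 (YJR025C, chromosome X), an enzyme of NAD synthesis from tryptophan, was lower in 16 mutants, with a mean log2 fold change of -1.01. YDR210C-D, a Ty element reading frame, was lower in 12 (mean -1.39), and YHL006W-A, a name without a match in the annotation, in 10 (mean -1.26). Reads placed at more than one site are not in the counts, so the total level of a Ty element was not measured. The mean of the 29 mutants against WT called 2 increases and 6 decreases, all of which rest on the same 4 WT libraries. In that comparison each of these 4 genes kept its call without any single WT library, without H3K4R S55 and with every other alternative tried.

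CYC1 was also the gene with the smallest p between the 22 mutants of H3 and the 7 of H4. This contrast, added after the data were seen, called 156 genes, 30 of them higher in the H3 mutants. Its error is the spread between libraries of a genotype, not the spread between strains, so a call can rest on few strains. HHF2, for example, was called here (log2 0.877), though against WT it was called higher in 3 mutants and lower in 2. Genotype means of CYC1 were 154 to 554 CPM in H3 mutants and 90.4 to 164 in H4 mutants, and the difference of the mean log2 level was 1.09 (two-sided permutation test, p = 1e-05, the smallest the permutations can give, on a gene chosen for this contrast). Of the H3 genotypes, 20 of 22 lay above every H4 genotype. Within sets this held for 11 of 15, 14 of 15 and 7 of 7. PDC5, a pyruvate decarboxylase, ADH2, the glucose-repressed alcohol dehydrogenase, and BNA1 were lower on average in H3 than in H4 mutants, by -0.74, -1.19 and -0.63 on the log2 scale. Their differences were not tested against the spread between strains.

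**Figure D2:**
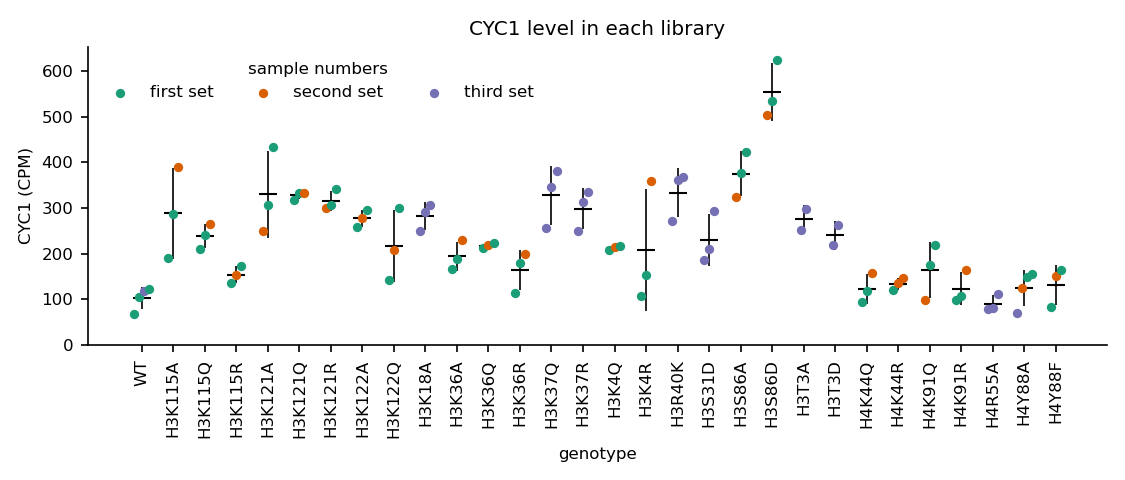
CYC1 level in CPM in every library, by genotype, with the genotype means. The lowest WT library stood at 66.8 CPM, and H3S86D had the highest mean, 554 CPM.

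H3K36A replaces the lysine that the enzyme Set2 methylates. HHF2 (YNL030W, chromosome XIV, 576727 to 577038), a gene of histone H4, stood at 508 ± 14.2 CPM (n = 3) in H3K36A against 55.4 ± 7.61 in WT (n = 4), 9.16 times as high (adjusted p = 3.3e-07). LAM5, a sterol transfer protein, rose from 51.1 ± 7.44 to 156 ± 10.2 CPM (log2 1.61), PGU1, a pectin-degrading enzyme, rose by 2.30 and HEF3, a translation elongation factor, by 1.07. IRC18, a gene linked to spore wall formation, dropped from 24.7 ± 8.33 to 3.3 ± 0.607 CPM (log2 -2.85), and BNA1 from 169 ± 28.9 to 48.9 ± 20.1 (log2 -1.79). Of 41 amino-acid synthesis genes under the activator Gcn4, 4 fell: HOM3 (aspartate kinase, -2.15), ARG5,6 (YER069W, arginine synthesis, -1.61), HIS1 (-0.94) and ARO4 (-0.80). Adjusted over the list alone, 13 fell (camera adjusted p = 4.45e-11, but adjusted p = 0.598 with an estimated correlation). WT libraries themselves spread widely for ARG5,6 (154 ± 143 CPM) and HOM3 (21.6 ± 19.4 CPM), and both calls were lost without some single libraries. In all, 29 genes rose and 16 fell. The count was 8 without H3K36A S50, 1.2e+02 (given to 2 digits) without WT S133 and 447 with the set as covariate, a fit in which all 45 genes were called too.

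In H3K36Q, YPR092W (3.42), PGU1 (2.32) and PUL3, a transporter gene (2.70), were among 23 increases, and IRC18 (-2.55), BNA1 (-2.08) and ARG5,6 (-1.47) among 10 decreases. The Gcn4 list had 3 of 41 decreases, 11 adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). H3K36Q called 12 genes without S53 and 67 with the set. H3K36R called 1 gene, BNA1 (-1.35), with 0 without S52 and 9 without S51. Compared directly, H3K36A differed from H3K36Q and from H3K36R in 1 gene each, HHF2, and H3K36Q from H3K36R in 0 by edgeR and 0 by DESeq2, with 98 genes at an unadjusted p under 0.05.

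H3K122A lies where the nucleosome binds DNA at its centre. SER3 (YER081W, chromosome V, 322686 to 324095), which catalyses the first step of serine synthesis, stood at 449 ± 41.1 CPM (n = 3) against 33.4 ± 8.11 in WT, a log2 fold change of 3.75 (adjusted p = 1.91e-16). GAS2, a glucan enzyme of the spore wall, rose by 1.84, MUP1, the high-affinity methionine permease, by 1.75, and CYC1 by 1.43. Counts at the genes of the non-coding RNAs snR78, snR6, snR73, snR65, snR56 and RPR1 rose by 1.19 to 1.78. Whether counts from a method for the 3′ ends of messenger RNA follow the level of such RNAs was not tested. Among 19 decreases, TAL1, an enzyme of the pentose phosphate pathway, dropped to 76.6 ± 13.7 CPM (log2 -1.71), FDC1, a decarboxylase of phenylacrylic acids, changed by -1.50, and GPA1, a subunit of the pheromone G protein, by -1.11. LEU2, of leucine synthesis, was at 555 ± 147 CPM (log2 -1.09). In the sulfur and methionine list 1 of 21 members rose, 5 adjusted over the list alone (camera adjusted p = 2.07e-07, adjusted p = 0.162 with an estimated correlation). The 45 calls became 11 without H3K122A S59 and 94 with the set, which called 43 of the 45.

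H3K122Q had SER3 at 334 ± 64 CPM (log2 3.32) as well, and in addition mating genes. Of 15 genes of the pheromone response, 5 rose, among them PRM3 (nuclear fusion, 3.07), FIG2 (a cell wall protein of mating cells, 2.13), FUS2 (cell fusion, 1.41) and KAR4 (a transcription factor, 1.23). Adjusted over the list alone 13 rose, and the list was called with the preset and with an estimated correlation (adjusted p = 1.48e-20, and adjusted p = 0.0058 with an estimated correlation). Between the 2 mutants 11 genes differed: FIG2 (-1.67) and NFG1 (-1.96) were lower and KEI1 (0.82) higher in H3K122A. None of the 11 remained called without H3K122A S60. H3K122Q called 28 genes, 11 without S62 and 61 with the set.

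Chromosome XI was raised along its whole length in H3K121R and H3K37Q, with a median log2 shift of at least 0.666 in each of 10 parts of it. Of 298 tested genes on it, 99% in H3K121R and 98.7% in H3K37Q lay above the median of all genes, and the median gene was 1.81 and 1.77 times its WT level. The shift was 0.718 to 0.928 on the log2 scale in the 3 libraries of H3K121R and 0.724 to 0.825 in those of H3K37Q. No other nuclear chromosome of these libraries shifted by more than 0.191, and 2 of 493 pairs of mutant and chromosome were called. The chromosome held 169 of the 223 increases of H3K121R and 163 of the 250 of H3K37Q, and none of their decreases. Among the genes on it were FBA1 and GPM1 of glycolysis, SDH1, SDH3 and ATP7 of respiration, MDH1 of the citric acid cycle and all 5 called ribosomal protein genes of H3K121R. With p values adjusted again without the genes of chromosome XI, H3K121R had 20 called genes instead of 255 and H3K37Q 59 instead of 299. Calls off the chromosome were lost in this step too. In the main test 54 increases and 32 decreases of H3K121R, and 87 and 49 of H3K37Q, were not on it. Leaving out H3K121R S78 gave 151 and leaving out H3K37Q S118 gave 168. With the set as covariate H3K37Q called 230 genes, 152 of them among the 299. With a minimum mean level of 50 CPM, the mitochondrial genome in H3T3D was called as well, at 0.556 to 0.562.

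**Figure D3:**
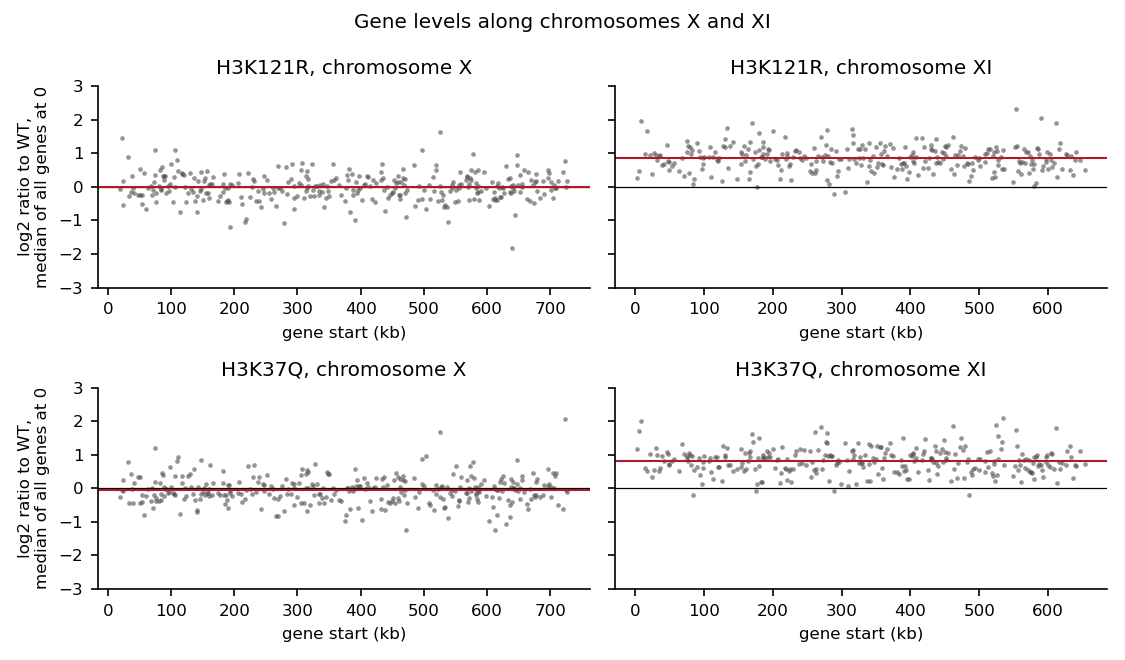
Log2 ratio to WT of each gene along chromosome XI in H3K121R and H3K37Q, with chromosome X beside it, by gene start and with the median as a red line. On chromosome XI 99% and 98.7% of 298 genes lie above the median of all genes.

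The purine synthesis list was called higher in 8 mutants with the preset correlation, and members of it were called in 5 of them. In H3K121Q, 10 of 14 members rose, among them ADE17 (560 ± 428 CPM, n = 3, against 44.4 ± 16.1 in WT, log2 3.66), ADE13 (2.29), MTD1 (folate metabolism, 2.26) and ADE1 (2.10). Counts of 5 in H3K121R, 3 in H4Y88F, 2 in H3S86A and 1 in H3K121A became 10, 12, 10 and 11 when adjusted over the list alone, and 12 in H3K121Q. The preset camera test called the list in each (adjusted p = 1.4e-18 in H3K121Q), the estimated correlation in none: adjusted p = 0.0636 with an estimated correlation in H3K121Q, and 0.725, 0.0512, 0.0601 and 0.232 in H3K121R, H4Y88F, H3S86A and H3K121A. The rise was in the libraries of the first set, with a lowest median of 1.08 on the log2 scale, and the library of the second set lay at -0.12 to 0.22. The other 3 mutants, H3K115Q, H3K4Q and H3K115R, had 5, 3 and 0 members higher when adjusted over the list alone (adjusted p = 0.863, 0.798 and 0.907 with an estimated correlation). First-set libraries of H3K115Q had medians of 0.87 and 1.05 and those of H3K4Q 0.56 and 1.07, against 0.01 and -0.16 in the second set. Respiratory genes rose in H3K121R as well, 7 of 38, of which QCR2, QCR10, ATP15 and CYC1 lie off chromosome XI (adjusted p = 0.725 with an estimated correlation). H3K121A called 2 genes, ADE17 (3.08) and CYC1 (1.68), but 33 without S108. H3K121Q called 59 genes, but 1 without S79 and 279 without S110, its library of the second set. H3K121A differed from H3K121Q in 0 genes by edgeR and DESeq2, with 254 at an unadjusted p under 0.05. It differed from H3K121R in 158, and H3K121Q from H3K121R in 150. With p values adjusted again without the genes of chromosome XI, 1 gene was called in each. Calls off the chromosome can be lost in this step too. The counts of 158 and 150 were 93 without H3K121A S75 and 73 without H3K121Q S80.

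HHF2 was the gene that set apart substitutions of H3K115 too. Its level was 779 ± 474 CPM in H3K115A (log2 3.82) and 1040 ± 94.8 in H3K115Q (log2 4.23), but 53.8 ± 15.1 in H3K115R, close to the 55.4 ± 7.61 of WT (n = 3, 3, 3 and 4). The 9 libraries of H3K36A, H3K115A and H3K115Q were all at 310 CPM or above, and the other 81 at 252 or below. The 252 CPM rest on 7 counts in H3K4R S55, and the highest of the others was 173 CPM. HHF1, the other gene of histone H4, was called in none of the 3, with log2 fold changes of -1.42, -0.95 and -0.46 in H3K36A, H3K115A and H3K115Q and WT libraries from 997 to 3120 CPM; with the set it was called in H3K36A (adjusted p = 0.0133). HHT2, the histone H3 gene beside HHF2, had log2 fold changes of -0.33, -0.29 and -0.63, none called, and without WT S133 of 0.11, 0.14 and -0.19, none called either. HHF2 was the only gene called between H3K115A and H3K115R and between H3K115Q and H3K115R. H3K115A against H3K115Q gave 0 by edgeR and DESeq2, with 289 genes at an unadjusted p under 0.05, close to a share of 0.05 of the 5822 genes. Against WT, H3K115A called 10 genes (5 without S63, 18 without WT S133), H3K115Q 9 (1 without S68), with SER3 at 1.47, MUP3 at 2.17 and MUP1 at 1.28, and H3K115R 2, YDR210C-D (-2.47) and YHL006W-A (-2.08), or 0 without S65.

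**Figure D4:**
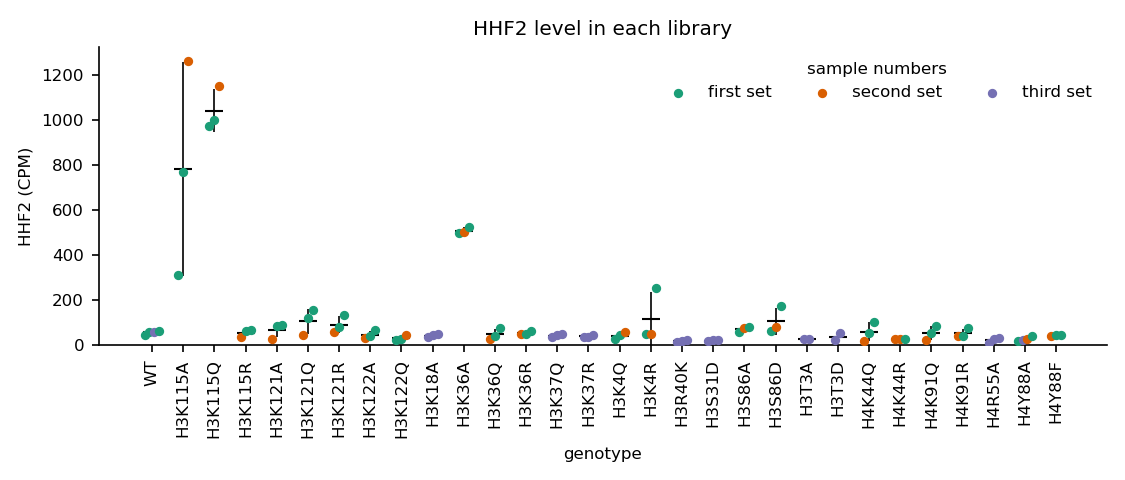
HHF2 level in CPM in every library, by genotype, with the genotype means. The 9 libraries of H3K36A, H3K115A and H3K115Q lie at 310 CPM and above, and the other 81 at 252 and below. The 252 CPM are from H3K4R S55, the library of low depth, and the next highest of the 81 is at 173 CPM.

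H3T3D had the most called genes of the stress list. HSP12 (YFL014W, chromosome VI), a membrane-stabilising stress protein, stood at 545 ± 8.19 CPM (n = 2) against 23.7 ± 10.3 in WT (log2 4.52, adjusted p = 1.88e-05). DAN1, a cell wall protein of anaerobic growth, rose by 4.70, DDR2, a stress gene, by 2.43, GAD1, glutamate decarboxylase, by 2.37 and ALD3, an aldehyde dehydrogenase, by 2.37. Of 34 genes of the environmental stress list 14 rose and 1 fell, 20 and 1 adjusted over the list alone (camera adjusted p = 3.08e-14, adjusted p = 0.236 with an estimated correlation), and 12 rose with the set. Ergosterol synthesis had 5 decreases of 24, such as ERG12 (-1.12) and ERG26 (-0.96), 7 adjusted over the list alone (adjusted p = 0.502 with an estimated correlation). In H3T3A 4 of the stress genes rose, HSP42 (2.21), GSY2 (1.72) and SPI1 (1.63) among them, and 1 fell, ALD2 (-1.45); 13 rose adjusted over the list alone (adjusted p = 0.303 with an estimated correlation). The ergosterol list had 4 decreases. H3T3D called 264 increases and 191 decreases, 237 genes in all with the set and 39 without S134, and its not-unique ratio was the highest of all genotypes, 8.04 ± 0.177 (n = 2) against 3.72 ± 0.963 in WT; H3T3A called 75, 64 with the set, 2 without S130 and 1.2e+02 (given to 2 digits) without WT S133. Only 166 of the 455 genes of H3T3D and 30 of the 75 of H3T3A were called with the set too. Between the 2 mutants 5 genes differed, all higher in H3T3D: DAN1, CPP3 and, named after their values were seen, TIR2, ALD3 and EUG1. None remained without H3T3A S130.

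H3R40K called 515 genes, among them members of the Gcn4, glycolysis and respiratory lists. Of the Gcn4 list 13 of 41 fell, such as HOM3 (-2.73), ARG1 (86.4 ± 10.1 against 527 ± 352 CPM, log2 -2.61) and ARG3 (-2.58), 20 adjusted over the list alone (adjusted p = 0.642 with an estimated correlation), and 5 with the set. Glycolysis had 5 decreases of 16, PGI1 (-1.53), TDH2 (-1.50) and CDC19 (-1.40) among them (adjusted p = 0.736 with an estimated correlation), but 0 with the set. Respiratory genes had 6 increases of 38, CYC1 (1.70), ATP14 (1.47) and ATP1 (1.38) included (adjusted p = 0.736 with an estimated correlation), and 10 with the set. Of the purine list 4 of 14 fell, GCV1, GCV2 and GCV3 by 1.38, 2.05 and 1.34 on the log2 scale among them, and 5 fell and 1 rose adjusted over the list alone (adjusted p = 0.736 with an estimated correlation), with 0 called with the set. Of 515 called genes, 253 were among the 437 called with the set, and 208 were called without S138. The not-unique ratio of these libraries was the lowest of all genotypes, at 1.41 ± 0.187 (n = 3).

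H3S31D called 307 genes, among them some ribosomal protein and glycolytic genes. Of the ribosomal protein genes 20 fell and 1 rose, among the former RPS19A (-1.88), RPS27B (-1.73) and RPL25 (-1.70), 50 and 2 adjusted over the list alone (adjusted p = 0.671 with an estimated correlation). PGK1 (-2.04), TPI1 (-1.74) and CDC19 (-1.62) were among 5 of 16 glycolytic genes that fell (adjusted p = 0.646 with an estimated correlation), and HOM3 (-3.32) among 13 of 41 of the Gcn4 list (adjusted p = 0.313 with an estimated correlation). RNR2 and RNR4, subunits of ribonucleotide reductase, changed by -1.49 and -1.47. With the set as covariate no member of these 3 lists was called in edgeR, and 41 genes were called instead of 307, 15 in both fits. The count was 6 without S139 and 467 without WT S133. Its not-unique ratio, 6.71 ± 0.898 (n = 3), was the second highest of all genotypes.

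H3K37Q had 5 of 34 stress genes higher, XBP1 (a transcriptional repressor, 1.80), HSP42 (1.74), DCS2 (1.31) and TPS2 off chromosome XI and GPX1 (1.78) on it; 12 were called adjusted over the list alone (adjusted p = 0.603 with an estimated correlation). CWP1, a cell wall protein also on chromosome XI, was higher by 1.66 on the log2 scale. H3K37R called 8 genes, CYC1 (1.54), GAS2 (1.27), IRC18 (-1.72) and BNA1 (-1.23) among them, 4 with the set, where GAS2, IRC18 and BNA1 were not called, 1 without S123 and 30 without WT S133. H3K37Q differed from H3K37R in 259 genes, with TSL1, a subunit of trehalose synthase, higher by 3.30 and IZH4, a membrane protein, lower by -2.37; 67 differed without chromosome XI and 143 without H3K37R S121. H3K18A called 6 genes, CYC1 (1.46), ERB1 of ribosome assembly (0.90), NUP116 of the nuclear pore (0.77) and BNA1 (-1.15) among them, 2 without S128 and 16 with the set, 2 of them in both fits and ERB1, NUP116 and BNA1 not among these. In H4R55A, 28 genes rose and 50 fell, the subtelomeric COS12 (1.52) and the cell wall enzyme GAS5 (-1.75) among them, but 5 were called with the set, COS12 and GAS5 not among them, 3 without S125 and 263 without S124.

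H3S86D raised CYC1 most (log2 2.43), with HSP12 (2.53), ALD3 (1.57) and the ribosomal protein gene RPS14B (1260 ± 76 against 346 CPM, 1.87). Histone genes HHT1 (1.67) and HHF1 (1.48) rose too, 2 of 10 in the histone list (adjusted p = 0.72 with an estimated correlation), and the call of HHF1 was lost with the set and with RLE. YKU80, of the end-binding Ku complex, changed by -1.42. It called 44 genes, 69 with the set and 14 without S113. H3S86A called 12, CYC1 (1.87), MUP3 (2.34) and MUP1 (1.40) among them, but 2 without S85 and 31 without S112. In H3S86A 1 of 21 sulfur and methionine genes rose, 9 adjusted over the list alone, and this list was called with both tests (adjusted p = 6.94e-11, and adjusted p = 0.0338 with an estimated correlation). Between both mutants 3 genes differed, FDC1 (1.17 higher in H3S86A), ALD3 (-1.76) and RCM1, an rRNA methyltransferase (-1.22), with 1 without H3S86D S87 and 8 without H3S86A S112.

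H3K4Q and H3K4R shared a rise of AGP1, a broad amino-acid permease (1.25 and 1.23), and of CYC1 (1.05 and 1.21). In H3K4Q ZRT1, the high-affinity zinc transporter, stood at 398 ± 326 against 68.2 ± 20.6 CPM (log2 2.54), and BNA1 (-1.34) and BDH1, butanediol dehydrogenase (-1.49), were lower. It called 18 genes, 143 with the set, 5 without S58 and 43 without WT S133. H3K4R, with the library of low depth, called 5, the others being TIR3 (1.61), BNA7 of NAD synthesis (-1.32) and RGD2 (-1.04), and 46 with the set. None remained called without WT S81, and 18 were called without S97. The 2 mutants differed in 0 genes by edgeR and DESeq2, with 142 at an unadjusted p under 0.05.

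In the H4 mutants, H4Y88A had YMR045C, a Ty element reading frame, at 59.2 ± 36.6 against 488 ± 193 CPM in WT (n = 4 each, log2 -3.04, adjusted p = 6.15e-12), its single called gene. These counts, too, leave out reads placed at more than one site. Without WT S46, 3 genes were called. H4Y88F called 4, ADE17 (3.14), ADE2 (2.07), MTD1 (2.06) and ADE1 (1.90), 0 without S74 and 35 without S107. Directly compared, they differed in 88 genes, ADE17 (-3.54) and YMR045C (-3.03) among them, in 2 without H4Y88F S74 and in 331 without H4Y88F S107. H4K44Q had 34 increases and 4 decreases, with PUL3 (3.08), PGU1 (2.96), RRT1 (2.61) and PRM3 (2.41) highest, and 23 calls without S93. H4K44R called 1 gene, PRM3 (2.50), 0 without S115, and differed from H4K44Q in 0 by edgeR and 1 by DESeq2, with 385 at an unadjusted p under 0.05. H4K91Q raised POT1, a thiolase of fatty acid oxidation (3.36), and RRT1 (51.3 ± 19.8 against 8.2 ± 7.31 CPM, 2.73), among 13 increases and 3 decreases, with 5 calls without S105. Among the genes eligible for naming, RRT1 also had the largest fold change between H4K91Q and H4K91R (log2 3.11). These differed in 9 genes, in 4 without H4K91R S69 and in 15 without H4K91Q S72.

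On average, profiles of 2 substitutions of one residue resembled each other more than those of different residues. The mean r across genes was 0.553 in 17 pairs of the first kind and 0.317 in 389 of the second, a difference of 0.236 (one-sided permutation test of the residue labels, p = 1e-05, the smallest the permutations can give). It was 0.339 with the set as covariate. Log2 levels centred on the mean of 21 genotypes were compared between first-set libraries of one mutant and the second-set libraries of the other. There the difference was 0.136 (p = 6e-05 by permutation), beside 0.365 for fold changes centred on the mean of the 29 mutants. Across these sets the mean r was 0.157 for a genotype with itself, 0.119 with another substitution of its residue and -0.017 with other residues. In simulated tables without differences, profiles over WT gave a difference of -0.0027 ± 0.0034, whereas their mean r over all pairs was 0.385 ± 0.0055 from the shared WT alone. Genes are not independent replicates. The highest r was 0.766, for H3K36A with H3K36Q, followed by 0.733 for H3T3A with H3T3D. Single pairs went the other way. H4Y88A with H4Y88F had 0.172 and H3K37Q with H3K37R 0.387, whereas H3K121A with H3S86A had 0.669 and H3K121Q with H4Y88F 0.645. Libraries of one residue mostly carry neighbouring sample numbers within a set, so residue and position are not fully separated. Pairs of different residues at most 26 numbers apart in the first set had a mean r of 0.326 (157 pairs). H3K36A and H3K122A had r = 0.298, where the shared WT alone gave 0.408 ± 0.0148 in simulation, and 0.024 with different WT libraries. The simulated tables hold no real changes between genotypes, so these values of r are not directly comparable. The covariance was 0.0697, against 0.0558 ± 0.0026 in simulation, and 0.0027 with different WT libraries. The correlation was 0.492 without WT S133 and 0.424 with the set as covariate, fits for which no simulation was run. It was negative after centring on the mean of the mutants (-0.205). H3K36A and H3K122A had 1 increase (snR72) and 1 decrease (BNA1) in common.

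**Figure D5:**
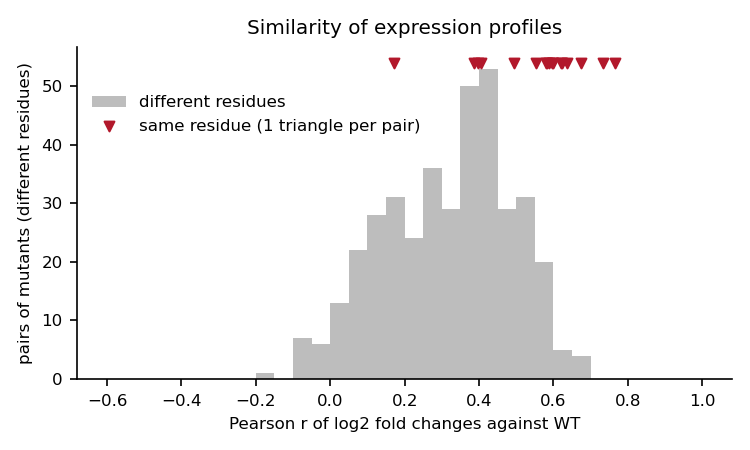
Pearson r across 5822 genes for each of the 406 pairs of mutants, by whether both substitutions are at one residue. The means are 0.553 for 17 pairs and 0.317 for 389 pairs.

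SAG1, the α-agglutinin, had 375 to 1170 CPM by genotype and MF(ALPHA)1, the α-factor, 304 to 827, whereas STE2, the α-factor receptor of a cells, had 1.86 to 7.7. AFB1, expressed in α cells, had 87.8 CPM or more in every genotype, and MATALPHA1 and MATALPHA2 had 0 and 1 counts over all libraries. HMLALPHA1 and HMLALPHA2, the α genes of the HML locus, had 1 and 2. Reads placed at more than 1 site are not in the gene counts, so these counts do not show that the genes are absent. CAN1, the arginine permease often deleted in laboratory strains, had 9 counts over all 90 libraries.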

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

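The tests on chromosome XI, HHF2 and the purine genes below, and the test of H3K36A with other splits, were chosen only after the result was seen.

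In WT and H4Y88A, which have 4 libraries each, depth, the not-unique ratio and the histone, marker and named genes gave 60 tests for a library that stands apart, and 4 found one, and chance alone gives about 1 in 20. HTB1 in H4Y88A S48 was 675 CPM where the other libraries had 188 to 217. HHT2 in WT S133 was 1.4e+02 CPM (given to 2 digits) where the others had 55.7 to 64.3. LYS2 in H4Y88A S132 was 235 CPM where the others had 312 to 321. YHL006W-A in H4Y88A S132 was 59.9 CPM where the others had 18.9 to 19.2.

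Of 17 pairs of substitutions of one residue, 12 differed in at least 1 gene. H3K121A against H3K121R differed in 158 genes (highest of the other splits 80), H3K121Q against H3K121R in 150 (238) and H3K37Q against H3K37R in 259 (0). H3K122A against H3K122Q differed in 11 genes (0), H4K91Q against H4K91R in 9 (0) and H3S86A against H3S86D in 3 (0). H3K115A against H3K115R, H3K115Q against H3K115R, H3K36A against H3K36Q and H3K36A against H3K36R differed in 1 gene each (0 each). The pairs without a call in edgeR had highest other splits of 0 (H3K115A against H3K115Q), 187 (H3K121A against H3K121Q), 1 (H3K36Q against H3K36R), 331 (H3K4Q against H3K4R) and 4 (H4K44Q against H4K44R), beside 289, 254, 98, 142 and 385 genes at an unadjusted p under 0.05 and 0, 0, 0, 0 and 1 by DESeq2. Without any difference, about 0.05 of the 5822 genes would have such a p. These 15 pairs have 10 splits each, too few for a share under 0.05. The splits of H3K121A and H3K121Q with 187 genes and of H3K4Q and H3K4R with 331 point to a structure of the samples. H3T3A against H3T3D differed in 5 genes, with 2 libraries each and no other splits run. H4Y88A against H4Y88F differed in 88 genes, and chance cannot be excluded, since another split of these libraries called 1.2e+02 (given to 2 digits).

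Genes of chromosome XI were higher in H3K121R and H3K37Q. A few strongly changed genes are excluded as the cause, since 98.7% or more of its genes lay above the median of all genes. Library depth or normalization is excluded, since no other nuclear chromosome of the 6 libraries shifted by more than 0.191 on the log2 scale. An additional copy of the chromosome in most cells could account for it, since the lowest median shift among 10 parts of the chromosome was 0.666. DNA was not measured here, and a count of DNA reads per chromosome in these strains would test it.

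HHF2 was higher in H3K36A, H3K115A and H3K115Q. Reads shared with HHF1 cannot be told apart from a change of HHF2. Mean HHF1 was lower by at least 51.3% of what HHF2 gained, but HHF1 was called only in H3K36A with the set as covariate. HHF2 and HHF1 varied together in H3K115A, at 1260 and 1520 CPM (S101), 768 and 949 (S63) and 310 and 385 (S64). They had 498 to 524 and 633 to 776 CPM in H3K36A, and 971 to 1150 and 1160 to 1430 in H3K115Q. WT libraries had 45.1 to 63.2 CPM of HHF2 and 997 to 3120 of HHF1. HHF2 thus stood near HHF1 in these 3 mutants and far below it in WT, and the cause was not tested. The highest HHT2 log2 change of the 3 mutants was -0.294, and 0.143 without WT S133 (H3K115A, standard error 0.401). These values argue against activation of the pair HHT2 and HHF2. They do not exclude it, given this error and because the build of the HHT2 copies is not known. A property of the residue stays open: the log2 changes of HHF2 in the other substitutions were -0.282 to -0.042, but they are those left after the 3 were chosen for HHF2, and 2 of the 3 substitutions of H3K115 raised it. How the strains were built could matter, and genotyping of both H4 genes would test it.

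Purine genes were higher in H3K121A, H3K121Q, H3K121R, H3S86A and H4Y88F. The library of the second set had at most 14.8% of the shift of the first, which argues against an effect of the substitution that is equal in both sets. An effect under all culture conditions is not excluded. Each genotype had 1 second-set library, that set had 0 WT libraries, and the labels do not give the culture conditions of the sets. The position of the libraries in the first set cannot be told apart from an effect of the strains. Libraries numbered next to these had a median shift of at most 0.208, but first-set libraries of H3K4Q (0.564 and 1.073) and H3K115Q (0.87 and 1.054) rose as well, and their second-set libraries (-0.155 and 0.011) did not. Culture conditions were not tested.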

How the results depend on the processing

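Chosen after the data were seen were the tests with the sample-number set as covariate, those without H3K4R S55 in comparisons that lack it, the comparisons of H3K121A or H3K121Q with H3K121R and of H3K37Q with H3K37R without the genes of chromosome XI, and the label permutation within sets. In what follows, each number is a count of genes called and the number in brackets after it is the count of the report. Counts written as 1.2e+02 are given to 2 digits. No paired analysis was possible because the columns carry no replicate number, so the planned test with the replicate as a block was not run. Counts stayed within 1.5 times those of the report for 39 of 47 comparisons with DESeq2, 44 of 47 with the RLE scaling and 47 of 47 without a filter on low counts. They did so for 12 of 46 with only the libraries of both genotypes and 21 of 47 with the set as covariate. Of 524 named gene and comparison pairs, 507 stayed called with DESeq2, 509 with RLE, 484 without the filter, 343 of 524 with the set and 157 of 511 with only both genotypes. None of the 524 turned its direction in these 5 alternatives. In 130 pairs the call held without any single library, and in 394 at least 1 omission ended it. H3K4R S55 held 24010 gene counts and the others 768398 to 3143681, and the spread between libraries of a genotype was 23.3% of a gene's level.

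With a model of only the libraries of both genotypes, which has far fewer libraries to estimate the spread, counts moved in 34 comparisons. H3K115A gave 3 (10), H3K115Q 2 (9), H3K115R 0 (2), H3K121A 0 (2), H3K121Q 0 (59) and H3K121R 27 (255). H3K122A gave 8 (45), H3K122Q 2 (28), H3K36A 5 (45), H3K36Q 2 (33), H3K36R 0 (1) and H3K37Q 110 (299). H3K37R gave 2 (8), H3K4Q 0 (18), H3K4R 0 (5), H3R40K 227 (515), H3S31D 90 (307) and H3S86A 4 (12). H3S86D gave 3 (44), H3T3A 1 (75), H3T3D 80 (455), H4K44Q 6 (38), H4K91Q 2 (16) and H4R55A 0 (78). H4Y88A gave 0 (1), H4Y88F 0 (4), H3K121A against H3K121R 0 (158), H3K121Q against H3K121R 0 (150), H3K122A against H3K122Q 0 (11) and H3K37Q against H3K37R 575 (259). H3S86A against H3S86D gave 0 (3), H3T3A against H3T3D 34 (5), H4K91Q against H4K91R 5 (9) and H4Y88A against H4Y88F 1 (88).

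The set as covariate moved 26 counts. H3K115A gave 47 (10), H3K115Q 27 (9), H3K122A 94 (45), H3K122Q 61 (28), H3K18A 16 (6) and H3K36A 447 (45). H3K36Q gave 67 (33), H3K36R 2 (1), H3K37R 4 (8), H3K4Q 143 (18), H3K4R 46 (5) and H3S31D 41 (307). H3S86D gave 69 (44), H3T3D 237 (455), H4K44Q 64 (38), H4K44R 5 (1), H4K91Q 28 (16) and H4R55A 5 (78). H4Y88A gave 2 (1), H4Y88F 8 (4), the mean of 29 mutants 14 (8), H3K122A against H3K122Q 21 (11), H3K37Q against H3K37R 393 (259) and H3S86A against H3S86D 14 (3). H4K44Q against H4K44R gave 9 (0) and H4Y88A against H4Y88F 299 (88). In this fit, the profile correlation of H3K36A with H3K122A was 0.424. The cause of each move was not tested.

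The mean of the 28 other mutants in place of WT moved 26 of 29 counts, with more libraries on the reference side. H3K115A gave 3 (10), H3K115Q 5 (9), H3K115R 0 (2), H3K121A 32 (2), H3K121Q 564 (59) and H3K121R 691 (255). H3K122Q gave 53 (28), H3K36A 291 (45), H3K36Q 88 (33), H3K36R 3 (1), H3K37R 21 (8) and H3K4Q 40 (18). H3K4R gave 16 (5), H3R40K 942 (515), H3S31D 789 (307), H3S86A 45 (12), H3S86D 205 (44) and H3T3A 158 (75). H3T3D gave 684 (455), H4K44Q 223 (38), H4K44R 16 (1), H4K91Q 73 (16), H4K91R 1 (0) and H4R55A 346 (78). H4Y88A gave 34 (1) and H4Y88F 1.2e+02 (4).

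DESeq2 moved 8 counts, the cause was not tested. H3K115Q gave 14 (9), H3K36R 3 (1), H3K4Q 41 (18), H3K4R 15 (5), H4R55A 158 (78) and H4Y88F 10 (4). H3K115A against H3K115R gave 2 (1) and H4K44Q against H4K44R 1 (0). The RLE scaling moved 3 counts, the cause was not tested. H3K121A gave 1 (2), H3K4R 8 (5) and H4K44Q against H4K44R 2 (0). A minimum log2 fold change of 1 leaves fewer genes by construction and moved 7 of 29 counts. H3K121R gave 142 (255), H3K36A 27 (45), H3K36Q 16 (33), H3K37Q 153 (299), H3R40K 230 (515) and H3S31D 172 (307). H3T3D gave 264 (455). Leaving out the genes of chromosome XI removes 298 tested genes and adjusts the unchanged p values of the others again, so calls off the chromosome can be lost as well. H3K121R gave 20 (255), H3K37Q 59 (299), H3K121A against H3K121R 1 (158), H3K121Q against H3K121R 1 (150) and H3K37Q against H3K37R 67 (259). The share of increases among the called genes moved by over 10 points for H3R40K (41.1% with DESeq2, 51.7% in the report), H3S31D (29.3% with RLE, 40.4%), H3S86D (65.8% with RLE, 66.7% with DESeq2, 79.5%) and H4R55A (25.3% with DESeq2, 35.9%). It also did so with DESeq2 in 5 comparisons of 11 or fewer genes: H3K36R, H3K37R, H3K115A against H3K115R, H3S86A against H3S86D and the mean of 29 mutants.

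The correlation of H3K36A with H3K122A was 0.298 in the report. It turned negative after centring each gene on the mean of the 29 mutants, at -0.205. It was 0.174 as Spearman's rho, 0.108 over the 1000 genes with the highest mean level and 0.024 with each mutant compared with a different pair of WT libraries. The last removes the WT libraries that both profiles share, and the cause of the other moves was not tested. Without single WT libraries it ranged from 0.27 (without S46) to 0.492 (without S133). The difference between substitutions of one residue and of different residues, 0.236, was 0.182 (without WT S133) to 0.246 (without WT S81). Of the 242 list calls with the preset correlation, 2 held with an estimated one, an alternative whose test allows for co-varying genes.

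Leaving out 1 library at a time gave these lowest and highest counts, where the remaining libraries of a genotype with a single one left are assumed to vary like those of the other genotypes. H3K115A gave 5 (without S63) to 18 (without WT S133), H3K115Q 1 (without S68) to 10 (without S103) and H3K115R 0 (without S65) to 2 (without S102). H3K121A gave 1 (without S75) to 33 (without S108), H3K121Q 1 (without S79) to 279 (without S110) and H3K121R 151 (without S78) to 360 (without S109). H3K122A gave 11 (without S59) to 46 (without H3K4R S55), H3K122Q 11 (without S62) to 34 (without S100) and H3K18A 2 (without S128) to 6 (without H3K4R S55). H3K36A gave 8 (without S50) to 1.2e+02 (without WT S133), H3K36Q 12 (without S53) to 35 (without WT S133) and H3K36R 0 (without S52) to 9 (without S51). H3K37Q gave 168 (without S118) to 323 (without WT S133), H3K37R 1 (without S123) to 30 (without WT S133) and H3K4Q 5 (without S58) to 43 (without WT S133). H3K4R gave 0 (without WT S81) to 18 (without S97), H3R40K 208 (without S138) to 538 (without H3K4R S55) and H3S31D 6 (without S139) to 467 (without WT S133). H3S86A gave 2 (without S85) to 31 (without S112), H3S86D 14 (without S113) to 65 (without WT S46) and H3T3A 2 (without S130) to 1.2e+02 (without WT S133). H3T3D gave 39 (without S134) to 469 (without WT S133), H4K44Q 23 (without S93) to 40 (without H3K4R S55) and H4K44R 0 (without S115) to 1 (without H3K4R S55). H4K91Q gave 5 (without S105) to 17 (without WT S133), H4R55A 3 (without S125) to 263 (without S124) and H4Y88A 1 (without H3K4R S55) to 3 (without WT S46). H4Y88F gave 0 (without S74) to 35 (without S107), H3K115A against H3K115R 1 (without H3K115A S63) to 2 (without H3K115A S101) and H3K115Q against H3K115R 1 (without H3K115Q S67) to 2 (without H3K115Q S103). H3K121A against H3K121Q gave 0 (without H3K121A S108) to 2 (without H3K121Q S110), H3K121A against H3K121R 93 (without H3K121A S75) to 181 (without H3K121R S109) and H3K121Q against H3K121R 73 (without H3K121Q S80) to 149 (without H3K4R S55). H3K122A against H3K122Q gave 0 (without H3K122A S60) to 14 (without H3K122Q S100), H3K37Q against H3K37R 143 (without H3K37R S121) to 270 (without H3K4R S55) and H3K4Q against H3K4R 0 (without H3K4Q S57) to 1 (without H3K4R S56). H3S86A against H3S86D gave 1 (without H3S86D S87) to 8 (without H3S86A S112), H3T3A against H3T3D 0 (without H3T3A S130) to 5 (without H3K4R S55) and H4K44Q against H4K44R 0 (without H3K4R S55) to 2 (without H4K44Q S117). H4K91Q against H4K91R gave 4 (without H4K91R S69) to 15 (without H4K91Q S72) and H4Y88A against H4Y88F 2 (without H4Y88F S74) to 331 (without H4Y88F S107). H4K91R stayed at 0 in edgeR without any single library, with DESeq2 and with the set, beside 167 genes at an unadjusted p under 0.05.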

Other observations

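The tests of CYC1 between H3 and H4 mutants and of H3K36A with other splits were chosen only after the result was seen.

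HXT3, a glucose transporter, fell in H3R40K (361 ± 99.7 CPM, n = 3, log2 -0.94), H3S31D (-1.30), H3T3A (-1.17, n = 2) and H3T3D (-1.11, n = 2), and with the set as covariate only the call in H3S31D remained. AMN1, which acts in daughter cell separation, fell in H3K37Q (-1.08), H3S31D (-1.37), H3T3A (-1.42) and H3T3D (-1.07), but in none of these with the set as covariate. COS12, a subtelomeric gene, fell in H3T3D (-3.58), H3K121Q (-2.73), H3K36Q (-2.58), H3S31D (-1.81) and H3R40K (-1.63), and rose in H4R55A (1.52); the calls in H3S31D, H3R40K and H4R55A were lost with the set. DUN1, a kinase of the DNA damage response, rose in H3T3A (1.15, lost with the set) and H3T3D (1.33). ZRT1, the zinc transporter, rose in H4K44Q (1.94) as in H3K4Q. CHA1, which breaks down serine and threonine, fell in H3T3A (-1.43) and H3T3D (-1.60).

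GAS2 rose in 9 mutants, and RRT1, the deacetylase gene HOS3 and the counts at the glutamate tRNA gene tE(UUC)L in 7 each. Whether these counts follow the level of the tRNA was not tested. AGP1, TIR3 and the checkpoint kinase gene TEL1 rose in 6 each. ARG5,6 fell in 8 mutants, FDC1 in 7 and ORT1, a transporter of ornithine, in 6. In all, 27 genes were called in at least 5 mutants.

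Of 899 pairs of list and mutant, 242 were called with the preset correlation, 2 of them with an estimated one, and 246 with the set as covariate, 174 of them called in the report in the same direction. In what follows the numbers are the mutants in which the list was called higher and lower. They were 12 and 11 for ribosomal proteins, 6 and 7 for ribosome biogenesis, 3 and 14 for Gcn4 amino-acid genes, 8 and 7 for purine synthesis and 4 and 2 for sulfur and methionine. They were 8 and 6 for glycolysis, 1 and 1 for glucose-repressed genes, 0 and 0 for hexose transporters and for galactose genes, 11 and 2 for the respiratory chain and 2 and 4 for the citric acid cycle. They were 5 and 10 for environmental stress, 2 and 9 for chaperones, 6 and 5 for iron, 8 and 2 for zinc, 0 and 1 for phosphate and 6 and 5 for ergosterol. They were 1 and 2 for cell wall integrity, 1 and 1 for G1/S, 4 and 3 for G2/M, 0 and 11 for M/G1 and 0 and 3 for DNA damage. They were 0 and 0 for a-specific genes, 2 and 2 for α-specific, 0 and 5 for haploid-specific, 3 and 6 for pheromone response and 2 and 8 for meiosis and sporulation. They were 6 and 3 for histones, 2 and 2 for subtelomeric genes, 1 and 1 for strain markers and 4 and 1 for genes with start sites within them.

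Among the splits of the libraries of mutant and WT, the real one called the most genes for H3K115R (2 genes, highest other 1), H3K122A (45, 19), H3K36Q (33, 6), H3R40K (515, 308), H3S31D (307, 231) and H4K44Q (38, 12). This share of 1 in 35 splits was not corrected over the comparisons, so it does not exclude chance. These splits do not hold the sample-number sets fixed: of the 515 genes of H3R40K, which lies wholly in the third set, 253 were called with the set, and H3K115R had 0 without S65. In H3K115Q, H3K121Q, H3K121R, H3K18A, H3K36A, H3K37Q, H3K37R, H3K4Q, H3S86D, H4K91Q and H4R55A the highest other split keeps the 3 mutant libraries together with 1 WT library, so it still holds what they share. The counts do not test the shift of chromosome XI in H3K121R and H3K37Q. For H3S31D the split with 231 sets the WT libraries of the first set against the third set, and 41 genes were called with the set as covariate. Chance also cannot be excluded for H3K115A (10, 62), H3K115Q (9, 16), H3K121A (2, 1047), H3K121Q (59, 409), H3K121R (255, 433), H3K122Q (28, 440), H3K18A (6, 12) and H3K36A (45, 175), where another split called as many genes or more. Nor can it for H3K36R (1, 2), H3K37Q (299, 314), H3K37R (8, 46), H3K4Q (18, 34), H3K4R (5, 518), H3S86A (12, 18) and H3S86D (44, 156). The same holds for H4K44R (1, 1), H4K91Q (16, 21), H4R55A (78, 181), H4Y88A (1, 718), H4Y88F (4, 48) and the mean of the 29 mutants (8, 1477). Splits with several times the real count, as in H3K115A, H3K121A, H3K121Q, H3K122Q, H3K36A, H3K4R, H3S86D, H4Y88A, H4Y88F and the mean, point to a structure of the samples. In H3K37R and H4R55A the highest split follows the sets, with 4 and 5 genes called when the set is a covariate. With 35 splits a share under 0.05 needs the real split to be the highest. H4K91R called 0 genes in edgeR and in DESeq2, beside 167 at an unadjusted p under 0.05, and the highest of its other splits was 0; with a real count of 0 the splits test nothing.

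The log2 sheet of the authors and the values fitted here had r of 0.643 (H4K91R) to 0.908 (H3T3D) across 5822 genes, with slopes of 0.253 to 0.718. HHF2 stood at 2.83 in H3K36A, 2.31 in H3K115A and 3.73 in H3K115Q in their sheet.

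One hypothesis is that substitutions in H3 raise CYC1 more than those in H4 do. It rests on an observation only: CYC1 was chosen because it had the smallest p of this contrast, so the permutation test (p = 1e-05, the smallest the permutations can give) restates the difference of 1.09 in mean log2 level and is no independent support. The ranges overlapped, with 20 of 22 H3 genotypes above every H4 genotype. Other differences between the 2 groups of strains were not tested, and a new set of H3 and H4 strains built in 1 background could test the hypothesis.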
